A study of Homo sapiens with 24 samples.

How the data were processed

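Messenger RNA levels were measured by RNA sequencing in 22Rv1, an established human prostate carcinoma cell line. Cells received vehicle (DMSO), KB02 or KB05, both compounds at 200 µM, and the labels give 3 h as the time point. Per the series design text, exposure to either compound lasted 1 h and was followed by 2 h in fresh medium, and treatments were done in biological triplicate. Column names of the table carry a 2 h tag, which was read as the recovery time. The labels give total RNA as the molecule, and the protocols name a spin-column RNA extraction and an Illumina library kit (NEBNext Ultra II RNA). Whether the libraries kept strand, and how ribosomal RNA was removed or messenger RNA selected, is not given in the sources used here. The series also lists 15 samples taken at 8 h with other compounds or vehicle, which were not analysed here.

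The values are estimated counts per gene, as the authors deposited them, with 1 column per library and no scaling to depth. Per the submitters' processing notes, the tools were Salmon 1.3.0 and DESeq2 1.30.1, and the named builds were hg38 and GRCh38.p13. Salmon divides reads among transcripts by a likelihood model, so reads of near-identical paralogs and of overlapping genes are split by estimate. The annotation release and the way transcripts were summed to genes are not given in the sources used here. Between 20.3% and 24.3% of values in a library were not whole numbers, and all were rounded to whole numbers before testing. The table holds 60232 Ensembl gene identifiers, of which 60064 matched the name table without regard to version and 41714 received a gene symbol. Gene positions come from GENCODE release 29 on GRCh38 and are counted from 1.

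Total counts per library ran from 15506975 to 21900548. A count of 3 in a library, used as the floor for genes with no reads, corresponds to 0.129 to 0.195 CPM, counts scaled to equal effective library size. These floors cover counting error only. Between replicates of a group, the chi-square per degree of freedom over genes lay between 4.43 and 10.6, so no pair of libraries agreed within sampling noise and all 9 were counted separately.

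Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 3 groups as grouping and a minimum count of 10, which left 18379 genes. Library sizes were scaled by TMM factors. A quasi-likelihood model with robust dispersion was fitted to all 9 libraries with the 3 groups and no block. Each comparison (KB02 against DMSO, KB05 against DMSO, KB05 against KB02) was a contrast of that fit, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. All adjusted p-values of single genes below are from this test. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of the F statistic. Intervals at 95% use that SE and the degrees of freedom of the fit. Levels are TMM-scaled CPM, given as the mean ± SD of 3 libraries.

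Genes are named by a rule fixed before the data were examined. For each comparison it takes the 8 largest rises and 8 largest falls among called genes with a symbol, a mean log2 CPM of at least 1 and no overlap between the libraries of the groups compared. Clone-like names, pseudogenes whose symbol ends in P or P with a number, and small RNAs and their hosts are passed over. ADAM1A, a pseudogene with another form of symbol, stayed in. The rule also takes, from each gene list, the 2 called members with the largest change and a mean log2 CPM of at least 1. The direct comparison adds the genes named in either comparison with DMSO. It passed over 1 gene, among the falls of KB05 against KB02, and identifiers without a symbol that would have ranked among the named genes numbered 1 to 3 per direction.

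In all, 21 gene lists were fixed before the data were examined. They cover stress responses (heat shock, NRF2, the integrated stress response, endoplasmic reticulum chaperones, metallothioneins, p53, NF-kB, hypoxia, immediate-early genes), prostate biology (androgen receptor targets, luminal markers) and cell growth (mitosis, DNA replication, histones, ribosomal proteins, proteasome, cholesterol synthesis). Zinc-finger genes, mitochondrially encoded genes, the SF3B splicing complex and markers of other cell types complete them. Lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01 between genes, adjusted over the 21 lists. The same test with a correlation estimated from the data and fry served as alternatives. Of the list calls, those of the zinc-finger genes in all 3 comparisons, of the histone genes in both comparisons that called them, and of the heat shock, integrated stress response, immediate-early and p53 lists for KB05 against DMSO also held with an estimated correlation. Counts of changed members are given over all genes tested and adjusted over the list alone.

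The similarity of the responses to KB02 and KB05 was measured across genes. Because both use the same DMSO libraries, 20 simulated data sets of unchanged groups gave the values that shared controls produce when no gene changes. With 3 control libraries the controls could not be split.

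The gene test was tested on simulated counts with known changes. For KB02 against DMSO (17463 genes in the simulated set) it recovered 42.4% of genes changed by 0.5 on the log2 scale, 66.7% of those changed by 1 and 86.8% of those changed by 2, and 5.76% of its calls were false. For KB05 against DMSO (17448 genes) the recovered shares were 46.2%, 70.2% and 89.7%, with 4.17% false calls. For KB05 against KB02 (17442 genes) they were 39.5%, 68.5% and 91.4%, with 8.39% false calls. Each simulation was a single draw with 54 to 76 changed genes per size of change, and the false shares rest on 6 to 12 calls. That is a far smaller share of changed genes than was called in the real data. These rates therefore do not carry over to the real calls.

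Alternatives fixed in advance were other scalings (RLE, upper quartile, library size only), no filter and a stricter filter on low counts, DESeq2 1.42.0, limma-voom, a fit of only the groups compared, stricter thresholds, the replicate number as a block, and leaving out each library in turn.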

Results

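Gene expression was profiled in 22Rv1 cells, a human prostate carcinoma line that expresses the androgen receptor, after treatment with DMSO, KB02 or KB05. KB02 and KB05 are small molecules known here by code name. The design asks which transcripts respond to each compound at 200 µM, 3 h after the start of treatment, and how far the compounds differ at matched dose and time. Each group held 3 libraries. Total counts were 17565188 to 19830340 for DMSO, 17216760 to 21900548 for KB02 and 15506975 to 19617207 for KB05. Groups separated on the first principal components, which held 37.3% and 29.7% of the variance of log2 CPM. KB02 libraries lay between 53.3 and 58.1 on the first component and all others below 0. KB05 libraries lay between -50.2 and -48.9 on the second component and all others above 0.

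KB02 raised the stress gene HSPA6 and the immediate-early gene FOS and lowered the transcripts of 3 cytochrome P450 enzymes of the CYP1 family by 27.6-fold to 89.1-fold. CYP1A1, which oxidises polycyclic aromatic compounds, fell 89.1-fold, from 940 ± 46.2 to 10.6 ± 1.25 CPM (SD, n = 3). HSPA6, a strictly stress-inducible HSP70, rose 19.8-fold, from 4.12 ± 1.12 to 80.6 ± 15.6 CPM, and FOS, an AP-1 transcription factor, rose 20.3-fold, from 25.2 ± 3.98 to 511 ± 13.5 CPM. MYC fell 6.2-fold, from 143 ± 12.7 to 23 ± 2.48 CPM. Of 18379 genes tested, 8470 changed, 4191 higher and 4279 lower with KB02 than with DMSO, and 1110 of the higher and 1154 of the lower ones changed at least 2-fold.

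Among the largest rises with KB02 were SOCS1, an inhibitor of cytokine signalling, with a log2 fold change of 4.53 ± 0.15 (SE; adjusted p = 2.46e-17), and SNAI1, a repressor of E-cadherin transcription, with 4.19 ± 0.18. FOSB rose by 4.10 ± 0.09 on the log2 scale, FOS by 4.35 ± 0.09 and HSPA1A by 4.30 ± 0.21. HSPA1A and its neighbour HSPA1B are nearly identical, so the split of reads between them is uncertain. C1S, a complement protease, rose from 0.392 ± 0.172 to 9.91 ± 4.14 CPM, and NHLH1, a neuronal transcription factor, from 0.339 ± 0.144 to 6.32 ± 1.2 CPM. FOS (ENSG00000170345.10) lies on chromosome 14 at 75278774 to 75282230, and SOCS1 (ENSG00000185338.6) on chromosome 16 at 11254405 to 11256200. C1S (ENSG00000182326.15) lies on chromosome 12 at 6988259 to 7071032 (all GRCh38, all annotated as protein-coding).

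Among the falls, CYP1A1 (ENSG00000140465.14, chromosome 15, 74719542 to 74725610) changed by -6.48 ± 0.11 on the log2 scale (adjusted p = 5.5e-22), and its neighbour CYP1A2 by -5.74 ± 0.14. CYP1B1 (ENSG00000138061.12, chromosome 2, 38066973 to 38109902) changed by -4.79 ± 0.12, from 79.1 ± 6.3 to 2.83 ± 0.4 CPM. MYC (ENSG00000136997.21, chromosome 8, 127735434 to 127741434) changed by -2.63 ± 0.08. SLC30A2, a zinc transporter, fell 8.52-fold and TCIM 6.72-fold. ADAM1A, annotated as a pseudogene, had 373 reads over the DMSO libraries and 0 over those of KB02, at least 47.5-fold lower against a floor of 3 counts per library. Its level was 0 in every KB02 and KB05 library. Whether its reads were instead assigned to other genes was not tested, so this fall is uncertain. The read-through locus FMC1-LUC7L2, which overlaps other genes and is therefore uncertain, was at 8.42 ± 4.35 CPM in DMSO and 0.283 ± 0.384 CPM in KB02. Its adjusted p of 0.0144 became 0.0627 without KB02 replicate 1.

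Heat shock genes rose together with KB02: 25 of 29 measured members rose and none fell (25 adjusted over the list alone), with a median log2 fold change of 0.91 (camera adjusted p = 5.48e-17). With an estimated correlation the adjusted p was 0.131. Immediate-early genes, which respond to signalling within minutes, had 24 of 32 members higher and 3 lower (25 and 3 adjusted over the list alone), a median of 1.28 and an adjusted p of 8.35e-12. The list's adjusted p with an estimated correlation was 0.0659. Its lower members included MYC and CCN2, the latter at -2.06 on the log2 scale. Of 30 targets of the integrated stress response, which acts through ATF4, 19 rose and 5 fell, also when adjusted over the list alone (adjusted p = 6.84e-06, and 0.076 with an estimated correlation). CHAC1, a glutathione-degrading enzyme, rose from 10 ± 2 to 72.1 ± 7.49 CPM and the transcription factor ATF3 from 45.3 ± 4.03 to 290 ± 13.9 CPM. Of 26 p53 targets 13 rose and 3 fell, the same counts adjusted over the list alone (adjusted p = 0.0124, and 0.076 with an estimated correlation). Its members went apart: PMAIP1, a pro-apoptotic BH3 protein, rose 4.29-fold, whereas GDF15, a stress-induced secreted factor, fell 3.41-fold.

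Endoplasmic reticulum chaperones and metallothioneins were lower with KB02. Of 25 chaperone and unfolded protein response genes 20 fell and 2 rose (20 and 2 adjusted over the list alone), with a median of -0.73 and an adjusted p of 1.46e-09, which was 0.0659 with an estimated correlation. The protein disulfide isomerases PDIA3 and PDIA6 changed by -1.37 ± 0.07 and -1.25 ± 0.07 on the log2 scale. Of 8 measured metallothionein and zinc-response genes 7 fell and none rose (7 adjusted over the list alone), with a median of -1.32 (adjusted p = 2.55e-05, and 0.076 with an estimated correlation). SLC30A1, which exports zinc, fell from 86.5 ± 2.68 to 31.7 ± 1.89 CPM, and MT1E from 67.2 ± 2.89 to 25.3 ± 3.87 CPM. MT1E belongs to a family of similar genes, so its reads may be shared.

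Zinc-finger (ZNF) genes rose as a group with KB02: 212 of 440 measured members rose and 49 fell (213 and 53 adjusted over the list alone), with a median of 0.32, an adjusted p of 1.42e-07 and 0.00236 with an estimated correlation. ZNF844 rose 9.3-fold and ZNF442 rose 8.19-fold. Mitochondrially encoded protein genes fell in 12 of 13 cases (12 adjusted over the list alone; adjusted p = 1.63e-05, and 0.398 with an estimated correlation), and their share of all counts was 14.6 ± 0.8% in DMSO and 11.7 ± 0.56% in KB02. MT-ND5 changed by -0.66 ± 0.08 and MT-ND3 by -0.71 ± 0.20 on the log2 scale. The MT-ND3 call (adjusted p = 0.0245) ended without DMSO replicate 1 (0.0633), 2 (0.0544) or 3 (0.0784) and without KB02 replicate 2 (0.0635), and in a fit of the 2 groups compared (0.0621).

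Smaller shifts passed the test for growth lists. DNA replication genes had 15 of 26 members lower and 2 higher (15 and 2 adjusted over the list alone; adjusted p = 0.00328, and 0.452 with an estimated correlation). Of its cyclins, CCNE2 fell 2.56-fold and CCNE1 rose 2.26-fold. Mitotic genes had 10 of 25 members lower and none higher (9 adjusted over the list alone; adjusted p = 0.011, and 0.368 with an estimated correlation), led by the proliferation marker MKI67, which fell 3.05-fold, and KIF23, which fell 1.65-fold. The mitotic call ended when libraries were scaled by size only (adjusted p = 0.0931). Cytosolic ribosomal protein genes had 27 of 85 members higher and 5 lower (21 and 5 adjusted over the list alone; adjusted p = 0.0172, and 0.671 with an estimated correlation), yet the members with the largest changes, RPL30 and RPL35A, fell by 0.73 ± 0.08 and 0.68 ± 0.12 on the log2 scale. That call ended without DMSO replicate 1 (adjusted p = 0.088) or KB02 replicate 3 (0.123).

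The other lists were not called for KB02. Of 34 NRF2 targets, genes of the oxidant response, 13 rose and 10 fell (13 and 11 adjusted over the list alone; adjusted p = 0.537), with HMOX1, which degrades haem, 5.41-fold and OSGIN1 2.88-fold higher. Androgen receptor targets numbered 4 higher and 11 lower of 27 (the same adjusted over the list alone; adjusted p = 0.121), with SGK1 3.01-fold higher and PLPP1 3.02-fold lower. Luminal markers numbered 4 higher and 7 lower of 14 (the same adjusted over the list alone; adjusted p = 0.205), with the epithelial adhesion molecule EPCAM 2.72-fold and the protease TMPRSS2 2.53-fold lower. Cholesterol synthesis genes numbered 9 higher and 11 lower of 25 (9 and 12 adjusted over the list alone; adjusted p = 0.537), with EBP and TM7SF2 lower by 2.75-fold and 2.64-fold. Replication-dependent histone genes numbered 11 higher and 3 lower of 45 (11 and 2 adjusted over the list alone; adjusted p = 0.264), with H3C14 3.47-fold and H2BC15 2.56-fold higher.

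NF-kB targets (5 higher and 5 lower of 21; adjusted p = 0.722), proteasome subunits (9 and 4 of 31; 0.513) and hypoxia targets (7 and 3 of 19; 0.264) were not called either. Adjusted over the list alone these counts were 6 and 5, 9 and 4, and 7 and 4. Medians of the NF-kB targets and proteasome subunits, -0.01 and -0.02, lie opposite to their means, 0.08 and 0.03, and to the direction of the test. ADM, a vasoactive peptide, rose 10.8-fold and the histone demethylase KDM3A 2.03-fold, NFKBIE rose 1.76-fold, PSMB2 rose 1.36-fold and PSMA6 fell 1.49-fold. CD83 was at 3.71 ± 1.64 CPM in DMSO and 1.84 ± 0.292 CPM in KB02, and its adjusted p of 0.00288 became 0.0829 without DMSO replicate 3. In the SF3B splicing complex 3 of 8 members rose and 1 fell, also adjusted over the list alone (adjusted p = 0.381), with SF3B1 1.37-fold and PHF5A 1.32-fold higher. Of 20 markers of other cell types 11 were measured, 3 higher and 3 lower (3 and 4 adjusted over the list alone; adjusted p = 0.513). Its median and mean, 0.02 and 0.04, were above 0 while the test pointed down. The monocyte marker CD14 rose from 0.541 ± 0.249 to 8.8 ± 2.62 CPM, and ALB, the gene of serum albumin, which these cells expressed at 884 ± 14.6 CPM in DMSO, fell 2.87-fold.

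These results rest on 3 libraries per group. With library size as the only scaling the median of all genes moved by 0.13 on the log2 scale and 63.8% of calls were higher, against 49.5% with TMM. Medians that changed sign with library size only were those of the androgen receptor targets (-0.09 to 0.04), NF-kB targets (-0.01 to 0.12) and proteasome subunits (-0.02 to 0.11), none of them called. The NF-kB median also crossed 0 with RLE scaling.

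**Figure D1:**
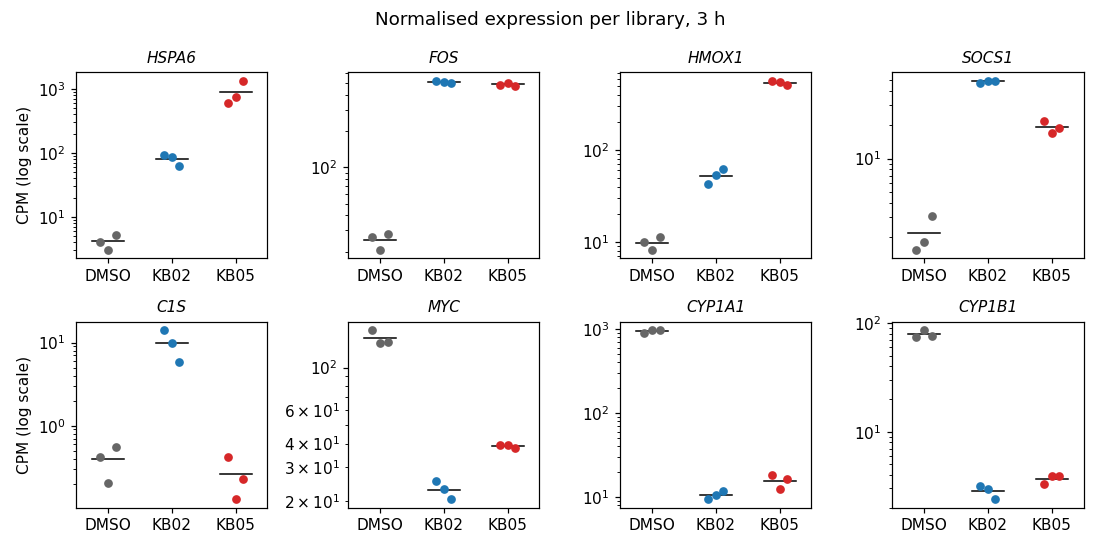
Each panel plots 1 gene, with TMM-scaled CPM on a log axis for the 9 libraries (points) and the mean of each group of 3 libraries (line). CYP1A1 lies at 940 CPM in DMSO and at 10.6 and 15.5 CPM with KB02 and KB05, FOS is nearly level between the compounds, and C1S is high with KB02 but not with KB05.

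With KB05 the stress genes HSPA6 and HMOX1 and the histone gene H3C14 were higher than with DMSO, and CYP1A1 was lower. HSPA6 (ENSG00000173110.8, chromosome 1, 161524540 to 161526910) rose 219-fold, from 4.12 ± 1.12 to 892 ± 395 CPM (SD, n = 3). HMOX1, which degrades haem (ENSG00000100292.18, chromosome 22, 35380361 to 35394214), rose 55.9-fold, from 9.77 ± 1.58 to 544 ± 28.5 CPM. The histone gene H3C14 (ENSG00000203811.1, chromosome 1, 149839538 to 149841193) rose 22-fold, from 2.48 ± 0.623 to 55.1 ± 0.808 CPM. CYP1A1 fell 60.3-fold, to 15.5 ± 2.87 CPM. In total 7321 of 18379 genes changed, 3434 higher and 3887 lower, of which 913 rose and 496 fell at least 2-fold. The balance of directions depended on scaling. It was 3766 higher and 3553 lower with upper-quartile factors, and 3589 and 3580 with library size only.

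The largest rises also held HSPA1A, at 6.17 ± 0.23 on the log2 scale (SE; adjusted p = 6.74e-07), and HSPA1B at 4.87 ± 0.12, whose reads are hard to divide. The synaptic immediate-early gene ARC rose by 5.08 ± 0.12, and the transcription factors EGR1 and EGR3 by 4.89 ± 0.14 and 4.49 ± 0.12. TDRG1, annotated as antisense and uncertain without strand, rose from 0.247 ± 0.164 to 6.06 ± 0.646 CPM. Among the falls, CYP1A1 changed by -5.91 ± 0.11, CYP1A2 by -5.25 ± 0.14 and CYP1B1 by -4.42 ± 0.11. GNRH1, the gene of gonadotropin-releasing hormone, fell 8.78-fold, from 4.26 ± 0.636 to 0.479 ± 0.0368 CPM. SULT1A3 fell 11.7-fold and the read-through SLX1B-SULT1A4 6.79-fold, both from near-identical segments of chromosome 16 and so uncertain. ADAM1A and FMC1-LUC7L2 had 0 reads in the KB05 libraries, at least 39-fold and 48.3-fold below DMSO against a floor of 3 counts per library. These bounds do not cover errors in the division of reads between genes, so both falls are uncertain. The FMC1-LUC7L2 call (adjusted p = 0.0108) ended with the replicate number as a block (0.0592).

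With KB05, 28 of 29 heat shock genes rose and none fell (28 adjusted over the list alone), with a median log2 fold change of 1.35 (camera adjusted p = 3.26e-31, and 0.0477 with an estimated correlation). Immediate-early genes had 30 of 32 members higher and 1 lower (the same adjusted over the list alone) and a median of 2.03 (adjusted p = 5.03e-35, and 0.00707 with an estimated correlation). The lower member was MYC, at -1.88 on the log2 scale. Of 30 integrated stress response targets 17 rose and 3 fell (18 and 3 adjusted over the list alone; adjusted p = 1.06e-08, and 0.0302 with an estimated correlation). ATF3 rose 10.3-fold, to 468 ± 11.1 CPM, and DDIT3, which encodes the pro-apoptotic factor CHOP, 9.36-fold, to 577 ± 16.1 CPM. Of 26 p53 targets 13 rose and 1 fell, also adjusted over the list alone (adjusted p = 2.21e-07, and 0.00707 with an estimated correlation), with the kinase gene PLK2 4.49-fold and PMAIP1 3.67-fold higher.

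Replication-dependent histone genes rose in 36 of 45 measured cases and fell in none (38 adjusted over the list alone). Their median was 1.68, with an adjusted p of 2.86e-18 and 0.00707 with an estimated correlation. H4C5 rose 16.1-fold, from 0.639 ± 0.0906 to 10.4 ± 1.46 CPM. These genes are similar in sequence, so values of single members are uncertain. Of 11 other RNAs without poly(A) tails, a list chosen after the results were seen, 5 were higher with KB05 and none lower, with a median of 0.73. Mitochondrial ribosomal RNA, measured beside them, took 3.17 ± 0.15% of counts in DMSO, 3.79 ± 0.05% in KB02 and 4.52 ± 0.23% in KB05. Zinc-finger genes numbered 139 higher and 67 lower of 440 (140 and 68 adjusted over the list alone; adjusted p = 0.0204, and 0.0302 with an estimated correlation), with ZNF844 5.96-fold and ZNF703 5.17-fold higher.

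Endoplasmic reticulum chaperones fell in 18 of 25 cases and rose in 2, also adjusted over the list alone (adjusted p = 5.65e-06, and 0.0673 with an estimated correlation). The members with the largest changes went apart: the co-chaperone DNAJB9 rose 2.13-fold and DERL1, of the degradation channel, fell 1.87-fold. Mitochondrially encoded protein genes fell in 12 of 13 cases (13 adjusted over the list alone; adjusted p = 3.5e-09, and 0.188 with an estimated correlation), with MT-ND2 and MT-CO3 changing by -0.91 ± 0.08 and -0.78 ± 0.08 on the log2 scale. Mitotic genes had 14 of 25 members lower and 1 higher, also adjusted over the list alone (adjusted p = 0.000729, and 0.188 with an estimated correlation), with MKI67 2.73-fold and KIF23 1.69-fold lower. DNA replication genes had 9 of 26 lower and 2 higher, also adjusted over the list alone (adjusted p = 0.0204, and 0.476 with an estimated correlation), with CCNE2 3.21-fold and POLE 2.1-fold lower. Ribosomal protein genes had 35 of 85 higher and 2 lower, also adjusted over the list alone (adjusted p = 5.65e-06, and 0.476 with an estimated correlation), with RPL35 1.37-fold and RPS12 1.33-fold higher.

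NF-kB targets (9 higher and 3 lower of 21; adjusted p = 0.0341) and hypoxia targets (5 and 1 of 19; 0.0341) were called for KB05 with the same counts adjusted over the list alone. With an estimated correlation their adjusted p-values were 0.376 and 0.286. Their medians were 0.15 and 0.07 on the log2 scale and their means 0.83 and 0.41, so a few members with large rises weigh on both lists. NFKBIE rose 2.38-fold, IRF1 2.03-fold, ADM 15.7-fold and ANKRD37 3.39-fold. The mean of the NF-kB list also rests on larger rises of members that the naming rule, with its cut on level, left out. Without DMSO replicate 1, DMSO replicate 2 or KB05 replicate 2 the NF-kB call ended (adjusted p = 0.0836, 0.0621 and 0.0549), and without DMSO replicate 2 or KB05 replicate 2 the hypoxia call did (0.059 and 0.0549).

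The remaining lists were not called for KB05. NRF2 targets numbered 11 higher and 8 lower of 34 (adjusted p = 0.217), with SQSTM1, an autophagy receptor, 1.76-fold higher. Metallothionein and zinc-response genes numbered 2 higher and none lower of 8 (0.206), with MT2A 1.43-fold and SLC30A1 1.22-fold higher, the latter with an adjusted p of 0.127 without KB05 replicate 1. Androgen receptor targets numbered 11 higher and 5 lower of 27 (0.0775, and 0.0339 without DMSO replicate 1), with SGK1 3.27-fold higher and PLPP1 1.82-fold lower. Luminal markers numbered 7 higher and 3 lower of 14 (0.118), with GATA2 2.12-fold higher and TMPRSS2 1.75-fold lower. Cholesterol synthesis genes numbered 5 higher and 5 lower of 25 (0.658), with EBP 1.6-fold lower. Proteasome subunits numbered 6 higher and 3 lower of 31 (0.538), with PSMD12 1.73-fold and PSMD6 1.25-fold lower. The SF3B complex numbered 1 higher and 2 lower of 8 (0.841), with SF3B1 1.42-fold lower and PHF5A 1.21-fold higher, a median of 0.02 and a mean of -0.03, and the test pointed down. Markers of other cell types numbered 1 higher and 2 lower of 11 (0.574), with ALB 1.48-fold lower and COL1A1 1.36-fold higher. Adjusted over the list alone, androgen receptor targets numbered 11 and 6, luminal markers 8 and 4, and the other 6 lists kept these counts.

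**Figure D2:**
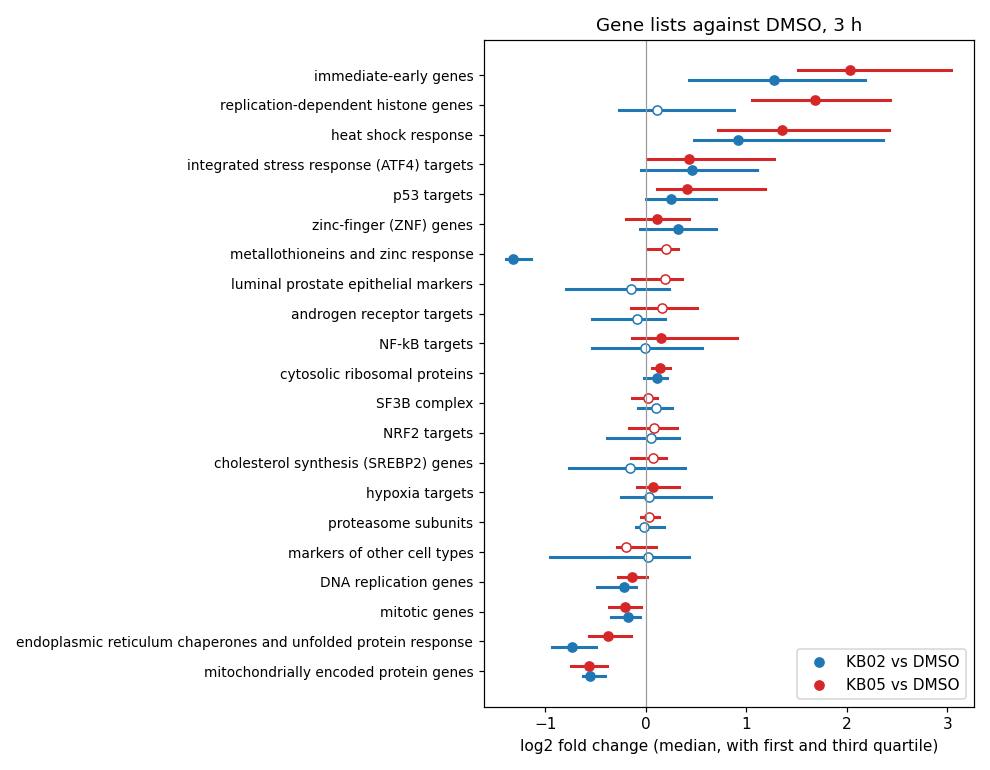
Median log2 fold change (points) and quartiles (bars) of the measured members of each of the 21 gene lists for KB02 against DMSO (blue) and KB05 against DMSO (red). Filled points passed the camera test at an adjusted p of 0.05. Metallothioneins lie at -1.32 with KB02 and 0.20 with KB05, and histone genes at 0.11 and 1.68.

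Tested directly at the same dose and time, KB05 left HMOX1 10.3-fold, the orphan receptor NR4A1 9.97-fold and HSPA6 11-fold above KB02. The zinc transporter gene SLC30A2 was 7.75-fold, the adhesion gene FLRT3 9.03-fold and the matrix-protein gene CCN2 8.5-fold higher with KB05. In the other direction, AOC3 was 47.7-fold, C1S 36.3-fold and CD14 22.5-fold lower with KB05 than with KB02. Of 18379 genes tested, 7346 differed, 3998 higher and 3348 lower with KB05, of which 756 and 962 by at least 2-fold.

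NR4A1 was at 37.9 ± 3.15 CPM in DMSO, 55.1 ± 3.16 in KB02 and 550 ± 55.1 in KB05. CCN2 and FLRT3 moved in opposite directions: CCN2 was at 26.3 ± 3.59, 6.25 ± 1.38 and 53.8 ± 6.07 CPM in DMSO, KB02 and KB05, and FLRT3 at 13.2 ± 1.24, 3.3 ± 0.126 and 29.9 ± 3.59 CPM. GDF15 (chromosome 19, 18374731 to 18389176) also fell with KB02 and rose with KB05, and differed by 2.47 ± 0.08 on the log2 scale (SE; adjusted p = 5.32e-21). H2BC8 and TDRG1 were 10.7-fold and 15.2-fold higher with KB05. Genes high with KB02 alone included AOC3, an amine oxidase gene, at 1.77 ± 0.414, 25.2 ± 3.1 and 0.539 ± 0.275 CPM in DMSO, KB02 and KB05. CHRNA10 was 25.9-fold, PYGM 21.4-fold, KCND1 18-fold and IQCN 14.2-fold lower with KB05 than with KB02. Part of these differences came from falls with KB05. Against DMSO, AOC3 was 3.34-fold, CHRNA10 4.01-fold, KCND1 3.09-fold and IQCN 1.92-fold lower with KB05, while PYGM was not called (adjusted p = 0.0863). SFT2D3, with an adjusted p of 0.042, was at 4.09 ± 1.42 CPM in KB02 and 0.152 ± 0.263 in KB05. Its call ended without any 1 of the KB02 or KB05 libraries (adjusted p from 0.0688 to 0.121) or without DMSO replicate 3 (0.0677), and with DESeq2 (0.0636).

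By list, KB05 exceeded KB02 for metallothionein and zinc-response genes (7 of 8 higher, none lower, also adjusted over the list alone; median 1.51; adjusted p = 2.28e-06, and 0.0558 with an estimated correlation). SLC30A1 was 3.33-fold and MT1F 3.06-fold higher. Histone genes were higher in 36 of 45 cases and lower in none (39 adjusted over the list alone; median 1.38; adjusted p = 4.13e-14, and 0.0201 with an estimated correlation), with H4C5 7.43-fold higher. Immediate-early genes were higher in 24 of 32 cases and lower in 2 (25 and 2 adjusted over the list alone; adjusted p = 1.47e-11, and 0.0558 with an estimated correlation). Endoplasmic reticulum chaperones were higher in 17 of 25 cases and lower in none (17 and 1 adjusted over the list alone; adjusted p = 1.08e-05, and 0.0811 with an estimated correlation), with PDIA6 1.83-fold and CALR 1.75-fold higher. Heat shock genes were higher in 13 of 29 cases and lower in 8 (14 and 8 adjusted over the list alone; adjusted p = 0.0219, and 0.628 with an estimated correlation), and SERPINH1, a collagen chaperone, was 4.05-fold higher. The members lower with KB05 included DEDD2 (1.75-fold), STIP1 (1.34-fold) and HSPH1 (1.33-fold). The heat shock call ended without KB05 replicate 3 (adjusted p = 0.0618).

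Prostate lists also differed. Androgen receptor targets were higher with KB05 than with KB02 in 16 of 27 cases and lower in 1 (17 and 1 adjusted over the list alone; adjusted p = 5.46e-05, and 0.199 with an estimated correlation). KLK3, which encodes prostate-specific antigen, was at 51.4 ± 3.66 CPM in DMSO, 35.7 ± 0.675 in KB02 and 65.5 ± 6.04 in KB05, and KLK2 at 87.2 ± 3.66, 69.7 ± 4.13 and 117 ± 5.07 CPM. Luminal markers were higher in 11 of 14 cases and lower in 1, also adjusted over the list alone (adjusted p = 0.000213, and 0.211 with an estimated correlation), with EPCAM 2.09-fold higher. p53 targets were higher in 12 of 26 cases and lower in 2 (13 and 5 adjusted over the list alone; adjusted p = 0.0158, and 0.0811 with an estimated correlation), with TP53I3 2.51-fold higher. Zinc-finger genes were lower with KB05 in 158 of 440 cases and higher in 40 (162 and 40 adjusted over the list alone; adjusted p = 1.08e-05, and 0.00544 with an estimated correlation), with ZNF547 8.48-fold and ZNF761 4.75-fold lower.

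No difference between the compounds was called for the other lists. NRF2 targets numbered 12 higher and 6 lower with KB05 of 34 (adjusted p = 0.316), integrated stress response targets 14 and 7 of 30 (0.325), NF-kB targets 8 and 2 of 21 (0.12), and cholesterol synthesis genes 12 and 8 of 25 (0.353). Proteasome subunits numbered 11 and 10 of 31 (0.625), hypoxia targets 8 and 2 of 19 (0.316), mitotic genes 1 and 4 of 25 (0.556), and DNA replication genes 8 and 3 of 26 (0.375). Ribosomal protein genes numbered 8 and 4 of 85 (0.316), mitochondrially encoded genes 2 and 4 of 13 (0.178), markers of other cell types 3 and 1 of 11 (0.428), and the SF3B complex 2 and 2 of 8 (0.316). Without KB02 replicate 3 or KB05 replicate 1 the ribosomal list was called higher (adjusted p = 0.047 and 0.0447), and without KB02 replicate 1 the mitochondrial list was called lower (0.036), as it was with library size only (0.022). Adjusted over the list alone, proteasome subunits numbered 11 and 11, mitotic genes 0 and 2, ribosomal protein genes 3 and 1 and the SF3B complex 2 and 3, and the other 8 lists kept their counts. Median and mean differ in sign for proteasome subunits (0.09 and -0.02, test down) and markers of other cell types (0.29 and -0.15, test up).

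Single members of these lists still differed. SLC7A11, the cystine transporter gene, was 2.49-fold lower with KB05 and VLDLR 1.99-fold higher. VEGFA was 1.89-fold higher and KDM3A 2.02-fold lower, DHCR7 and TM7SF2 were 1.82-fold and 1.85-fold higher, and NFKBIA and LIF 1.64-fold and 1.73-fold higher. SF3B1, a core splicing factor, was at 159 ± 4.23 CPM in DMSO, 218 ± 15.2 in KB02 and 112 ± 2.51 in KB05, 1.95-fold lower with KB05 than with KB02. PSMD12 was 1.71-fold and PSMD7 1.39-fold lower, CCNE1 2.1-fold and POLE 1.41-fold lower, KIF20A 1.28-fold and MT-ND1 1.4-fold lower, and RPL30 1.4-fold and ALB 1.94-fold higher with KB05. HMMR, RPL17, SF3B6 and MT-ND5 were called with changes of -0.34, 0.35, 0.23 and 0.28 on the log2 scale. Each of these last calls ended without at least 1 library: HMMR without KB05 replicate 3 (adjusted p = 0.078), and MT-ND5 without KB02 replicate 2 (0.104). RPL17 lost its call without DMSO replicate 1 (0.0582), KB02 replicate 1 (0.113) or KB05 replicate 3 (0.0563), and SF3B6 without DMSO replicate 2 (0.0668), KB02 replicate 1 (0.165), KB02 replicate 2 (0.0509) or KB05 replicate 2 (0.0962). Both calls also ended with library size only (RPL17 0.102, SF3B6 0.266), and that of RPL17 in a fit of the 2 groups compared (0.155).

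Several strong responders were close between the compounds. The direct log2 difference, KB05 over KB02, was -0.07 for FOS (95% interval -0.23 to 0.09), 0.13 for CHAC1 (-0.06 to 0.32), -0.12 for DNAJB9 (-0.31 to 0.07) and 0.02 for ZNF703 (-0.20 to 0.23). It was -0.11 for GATA2 (-0.25 to 0.02), 0.12 for SGK1 (-0.19 to 0.43), 0.16 for MKI67 (-0.02 to 0.35) and -0.03 for KIF23 (-0.20 to 0.15). CYP1A1 was 1.48-fold higher with KB05 than with KB02 (adjusted p = 0.000414), while the differences of CYP1A2 (0.49, interval 0.04 to 0.94, adjusted p = 0.093) and CYP1B1 (0.36, interval 0.05 to 0.67, adjusted p = 0.0561) did not pass after adjustment. With library size as the only scaling the median of all genes moved by -0.11 on the log2 scale and 37.4% of the calls were higher with KB05, against 54.4% with TMM. Medians of NRF2 targets (0.08 to -0.03), proteasome subunits (0.09 to -0.03) and ribosomal proteins (0.05 to -0.06), all without a call, changed sign with it.

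Across genes, 2024 were higher with both compounds than with DMSO, 2432 lower with both, and 512 changed in opposite directions (402 higher with KB02 and lower with KB05, 110 the reverse). Independent lists of these sizes would share 783 higher, 905 lower and 1686 opposite genes. Pearson's correlation of the log2 fold changes across genes, which are not independent replicates, was 0.51, and 0.50 in simulated unchanged groups against the same controls. Spearman's correlation was 0.53 against 0.46, and the sign was shared by 71.0% of genes against 66.7%. In the simulated groups all differences were noise, a large part of it from the shared controls. Their correlations and shared signs are therefore no baseline for groups in which many genes changed. The amount that the controls add is better read from the covariance. The covariance was 0.32 against 0.03 simulated, a difference of 0.29. With 3 shared DMSO libraries part of the overlap may come from the controls.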

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

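All alternatives here were fixed before the data were examined. Counts of changed genes stayed within 1.5 times the main value under every scaling, filter, tool and left-out library tried. The exception was the added demand for a log2 fold change of at least 1, which left 2264 genes for KB02 against DMSO, 1409 for KB05 against DMSO and 1718 for KB05 against KB02, by construction. Leaving out 1 library gave 7692 to 8507, 6174 to 7515 and 6314 to 7716 genes. DESeq2 called 7577, 6386 and 6425 genes. No call was made in the opposite direction under any of these settings, and DESeq2 kept 87.1%, 84.5% and 83.8% of the calls. The correlation between the responses ran from 0.473 to 0.567 without 1 library and rose to 0.630 among genes with a mean log2 CPM of at least 3. The cause was not tested.

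Of 2355 alternative values for 157 named results, 2324 kept the call and none changed sign. The 31 others belonged to 10 results, which are those of FMC1-LUC7L2, CD83, MT-ND3, SLC30A1, SFT2D3, HMMR, RPL17, MT-ND5 and SF3B6. Among the gene lists no call reversed, though medians near 0 of lists without a call changed sign under some settings, and an estimated correlation ended 24 calls, while fry ended 2 and added 18. Without a filter on low counts androgen receptor targets were called lower for KB02 (adjusted p = 0.0239) and higher for KB05 (0.0474), as were luminal markers for KB05 (0.0496), and for KB05 against KB02 NF-kB targets (0.0235) and ribosomal proteins (0.0467) were called higher.

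Whether replicate numbers pair the samples is not settled. Deviations of same-numbered libraries correlated only weakly, between -0.041 and 0.081. Yet 7 of 9 libraries correlated best with a library of their own number, a hint towards pairing from the data only. With the replicate number as a block, 8600, 7476 and 7518 genes were called, FMC1-LUC7L2 and SFT2D3 lost their calls, and the mitochondrially encoded list was called lower for KB05 against KB02 (adjusted p = 0.0455).

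Other groupings of 3 against 3 libraries make 10 splits, too few for a share under 0.05. In each comparison 1 of the 10, the real one, reached its own count. The real splits gave 8470, 7321 and 7346 genes and the highest other splits 0, 0 and 2. A count of 3 equals 0.129 to 0.195 CPM.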

Other observations

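The groupings by gene type (with its scalings), gene length and neighbouring genes (with the unmatched counts), and the tests of scaling, a stop of transcription, shared reads and S phase, were chosen after the results they bear on had been seen. Of 2597 long non-coding genes tested, 455 rose and 229 fell with KB02, and 485 rose and 257 fell with KB05. Of 14396 protein-coding genes 3441 were higher and 3951 lower with KB02, and 2731 higher and 3478 lower with KB05. The split of protein-coding genes for KB02 turned to 3932 higher and 3568 lower with upper-quartile factors and to 4769 and 3016 with library size only, while long non-coding genes stayed mostly higher, with 510 and 200, and 606 and 164.

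Among the protein-coding genes with the shortest span (median 5.26 kb), 888 of 2881 rose and 524 fell with KB05, and the median log2 fold change was 0.10. Among those with the longest span (median 165 kb), 312 of 2879 rose and 755 fell, with a median of -0.11. With KB02, 759 rose and 807 fell among the shortest and 687 rose and 620 fell in the longest, with medians of -0.01 and 0.03. In the direct comparison the medians, KB05 over KB02, were 0.17 for the shortest genes (quartiles -0.08 and 0.49) and -0.07 for the longest (-0.38 and 0.23). The difference between these overlapping groups was not tested.

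CYP1A1, CYP1A2 and CYP1B1, classic targets of the aryl hydrocarbon receptor, were among the largest falls with both compounds. Scaling did not account for it: the smallest of the 6 falls over 4 scalings was -4.39 on the log2 scale. A stop of transcription at every gene is argued against by the immediate-early list, whose lower median was 1.28. MYC, a member of that list, went the other way, at -2.63 with KB02 and -1.88 with KB05 on the log2 scale. Members of the list respond to signalling, so their rise cannot exclude a fall of transcription at most other genes. Counts scaled to equal library size do not show a change in total RNA either. Lower receptor activity stays open. Of 11 other receptor targets, listed before this test was run, 9 were measured, and the higher of their medians was -0.223, with 1 higher (TIPARP) and 3 lower (ABCG2, CCNG2 and SCIN) with KB02, and 1 higher (TIPARP) and 2 lower (ABCG2 and CCNG2) with KB05.

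Of 786 genes that were low in DMSO (under 5 CPM) and rose at least 2-fold with KB02, 174 (22.1%) had a same-strand gene of at least 10 CPM ending within 10 kb upstream, against 8.79% expected from genes that did not rise, weighted to the same levels in DMSO, a ratio of 2.52 (95% interval 2.19 to 2.85, one-sided permutation p = 1e-04, the smallest that 10000 permutations can give), while for a same-strand gene downstream the ratio was 1.17. For genes raised by KB05 the weighted upstream ratio was 0.526 (0.397 to 0.665), against genes that include those raised by KB02 alone. Likewise, the weighted ratio of 2.52 for KB02 was taken against genes that include those raised by KB05 alone. Genes near 0 CPM in DMSO passed the low-count filter mostly through their levels with a compound, which shapes the weighted comparison at the lowest levels. Both intervals held the expected share fixed. Unweighted, against 501 of 5007 low genes raised by neither compound (10%), the ratio was 2.21 for KB02 and 0.814 for KB05, and among genes of at least 1 CPM in DMSO it was 1.9 and 0.979. AOC3 starts 7426 bp behind PSME3, PYGM 4309 bp behind SF1, CD14 5039 bp behind NDUFA2, KCND1 2151 bp behind GRIPAP1, IQCN 5251 bp behind JUND and NHLH1 8115 bp behind NCSTN, while C1S, CHRNA10, SFT2D3, SOCS1, SNAI1 and HSPA6 have no such neighbour. Genes that overlap the start of the raised gene were not counted as neighbours. The lack of a counted neighbour therefore does not exclude an overlapping upstream gene. DNA in the KB02 libraries is argued against by low genes without an expressed gene within 50 kb, whose median was -0.0356 (2201 genes). Here low means an average under 5 CPM over all 9 libraries, KB02 included, so genes that KB02 raised strongly may be left out. A candidate explanation is transcription that runs on past the end of the upstream gene with KB02, as a hypothesis found and tested on the same data.

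For the rise of replication-dependent histone genes with KB05, a shift of reads among the 45 measured genes alone is argued against by their summed level. It rose from 240 ± 5.92 to 543 ± 11.9 CPM, 1.18 on the log2 scale, against 260 ± 4.82 CPM in KB02. That rise was foreseeable, since 36 of the 45 genes were higher and none lower. A shift of reads from copies outside these 45 genes was not covered, and 66 genes are in the list. More cells in S phase could raise the DNA replication list, whose median was -0.139. KB05 may change these transcripts by itself, so the list cannot tell the share of cells in S phase. Better capture of RNA without poly(A) tails in the KB05 libraries stays open: 11 other such RNAs had a median of 0.729, between the values that would argue for and against it, with 5 higher and none lower. The median is the value of RN7SK, which varied widely (6.85 ± 5.97 CPM in DMSO, 11 ± 13.1 in KB05). Most members were at low levels, and the most abundant, RN7SL1 and RN7SL2, changed by 0.41 and 0.48 on the log2 scale. RNU1-1 rose by 3.77 on the log2 scale, from 0.171 to 2.34 CPM. A release of histone transcripts with tails could not be tested with counts per gene.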
